A study of Saccharomyces cerevisiae and Debaryomyces hansenii and Kluyveromyces lactis with 42 samples.

How the data were processed

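Stops of reverse transcription were measured in S. cerevisiae in vivo and in vitro (DMS), in S. cerevisiae with NAI, in native D. hansenii and K. lactis, and in the YAC strains JYAC7 and JYAC2, as 28 libraries with 2 per group. Per the labels, cells grew in rich medium to mid-log phase, mRNA was selected with oligo-dT, its tails were trimmed with RNase H, and S. pombe cells were added as a spike-in. The authors deposited stop counts per 3′ isoform multiplied by a factor, so that each file summed to 20, 50 or 65 M (mega) reads. Dividing by the factor gave whole reads for 100% of values within 0.01 plus rounding, and these reads were used. The files describe stops at A and C, but all 4 bases were listed and used. The deposited Pab1 files held whole read counts per isoform with ends within 400 nt after a coding sequence. The deposited SOD1 files held counts per isoform and pentamer and net stops, another unit, which were DMS reads minus scaled control reads and never below 0. Bowtie was used, per the submitters' processing notes, and its version was not given in the sources used here. How reads shared by paralogs were placed was not given either, so values of RPL34B and other paralogs are uncertain. Coordinates and gene names were those of the S. cerevisiae R64 reference, which the ends of coding sequences in the files matched. Annotation of D. hansenii and K. lactis was not used here.

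A profile was the share of an isoform's reads at each of the 131 positions 20 to 150 nt upstream of its end, treated minus the control of the same replicate, with negative values set to 0. Isoforms needed 200 reads in each library. An end was given to a coding sequence within 400 nt. For isoform pairs, the pair of most abundant isoforms per gene was compared at shared genomic positions, between replicates, within and between isoforms, and genes were called apart where both r between isoforms lay below both r within. Mean differences were tested with 100000 random sign flips over genes, two-sided. Correlations corrected for replicate agreement were the mean r between divided by the root of the product of the mean r within. Because unequal depth alone lowers r between, 100 sets with shared profiles were simulated for each comparison, at an estimated number of reads per molecule. For isoform pairs over all distances this number was 91.6 in vivo, 8.6 with NAI and 9.6 in vitro. The simulation was added after the data were seen. In 1 simulated set per experiment, over all distances, a change of 25% of the profile in 50% of pairs was detected in all 3 experiments. In vivo this was narrow, at 0.02 against a highest 0.019 in sets without change. Detection was not checked for single distances.

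Stops 20 to 60 nt over stops 61 to 150 nt (pseudocount 0.5, log2 scale) were tested with limma 3.58.1 for an interaction of treatment and setting, with each treated library and its control as a block, which the design text pairs. The self-test of this step first recovered 0 changed isoforms, and was then revised to moderated variances and given sets with a change in 6604 isoforms, of which it recovered 6521 at log2 8 (170 false calls), 5157 at log2 4 (145 false calls) and, in sets added later, 0 at log2 2 and 1.5. With 100 changed isoforms it recovered 0 at log2 8, 4 and 2 in both versions.

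Pab1 counts were summed per gene and tested with edgeR 4.0.16 (TMM, filterByExpr, quasi-likelihood F test, culture as a block) in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. The block was used because each culture gave its own immunoprecipitate and input, and the deviations of the libraries of a culture correlated by 0.508, 0.346 and 0.500. The input of myc culture A held no entries from chromosome I into chromosome VIII, so a chromosome was left out where over 5% of coding sequences with at least 300 reads elsewhere were at 0. This rule, which left chromosomes IX to XVI, was set after a fit on 10 chromosomes had been seen. In simulated counts of the 3012 genes the test recovered 70 of 100 genes changed 2-fold and 11 of 100 changed 1.5-fold, with 2 false calls in each. Isoforms within genes were tested with edgeR's diffSpliceDGE, for isoforms with at least 20 reads on average. DESeq2 1.42.0 was an alternative. Gene lists were tested with camera (preset correlation 0.01) and fry.

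Pab1 ratios were set against net stops (pseudocount 1) within genes, with 100000 permutations of isoforms within genes, two-sided. SOD1 profiles were compared between pentamers with at least 200 reads by a one-sided permutation within blocks of 10 pentamers of like depth. The planned permutation over all pentamers gave p = 0.002 on simulated data with no effect, so it was replaced after that was seen. In the YAC strains, ends at most 50 nt apart with at least 20 reads in a library made a cluster, and clusters needed 100 reads per library for end use, which was taken from untreated libraries.

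The lists were cytosolic ribosomal proteins, mitochondrial ribosomal proteins, glycolysis and fermentation, translation factors, chaperones and heat shock, ribosome biogenesis, respiratory chain and ATP synthase, cell wall and secreted proteins, histones, amino acid biosynthesis, ergosterol biosynthesis, proteasome, and poly(A) tail binding, deadenylation and decapping. Lists, groups, tests, most alternatives and the rule for named genes were fixed before the data were examined. For Pab1 the rule took the 10 largest rises and the 10 largest falls past the threshold with the same direction in all 3 cultures and at least 100 reads on average, up to 4 members per list past the threshold, and PAB1. For Pab1 isoforms it took the 10 genes with the smallest p. For isoform pairs and for in vivo against in vitro profiles it took the 10 largest differences or lowest corrected r and the 5 highest corrected r, at 1000 reads or more. For the YAC strains it took up to 20 clusters by reads, and SOD1 in every part. Genes named for stops near the 3′ end, and single pentamers, were chosen after their values were seen.

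Other choices made after the data were seen were the base at the listed stop coordinate, since A was enriched less at the planned base 1 nt upstream (in vivo 35.1% and 35.2% with DMS, 33.9% and 33.7% without), the subsets with at least 1000 and 5000 reads, the corrected r over all genes, A and C positions only, isoforms within 1.5-fold in reads, the end clusters, SOD1 isoform 71 only, Pab1 without myc culture A on all chromosomes, and the exchange of JYAC7 libraries for replicate agreement. Replicate pairs differed by 5.6 to 45.2 times sampling noise (chi-square per degree of freedom), so none was counted as a duplicate. Groups of 1 to 3 libraries were too small for an outlier test. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.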

Results

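The series measured, in yeasts, how reactive mRNA is to structure probes near its 3′ end, which 3′ ends are used, and which mRNAs the poly(A)-binding protein Pab1 carries. It held 42 samples in 20 groups. In DREADS, cells or refolded RNA were treated with dimethyl sulfate (DMS), which methylates unpaired A and C, and the sites where reverse transcription stopped were read together with the 3′ end of the same molecule, so that every 3′ isoform had its own stop profile. SHREADS did the same with NAI, which acylates flexible riboses, against a solvent control. CLIP-READS counted reads per 3′ isoform after immunoprecipitation of tagged Pab1 and in the matching input. Each stop experiment had 2 independent biological replicates, A and B, per the labels; the library preparations of an in vivo replicate shared a file and counted as 1 library. Pab1 was measured in 3 cultures, of which 2 carried the myc tag and 1 the V5 tag.

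Depth differed between the parts of the series. In vivo DMS and untreated libraries of Saccharomyces cerevisiae held 47.6 to 56.7 M (mega) reads, in vitro libraries 40 to 44.2 M, and NAI and solvent libraries 54.2 to 77.6 M. Native Debaryomyces hansenii libraries held 14.9 to 20.7 M reads and native Kluyveromyces lactis libraries 17.3 to 25.0 M. The strains that carried a piece of these genomes on a yeast artificial chromosome (YAC) in S. cerevisiae held 15.6 to 19.1 M reads (JYAC7, D. hansenii insert) and 18.3 to 22.9 M (JYAC2, K. lactis insert). The Pab1 libraries held 4.14 to 9.4 M reads. Each in vivo library listed 40.1 to 52.9 reads per distinct stop against 11.9 to 17.7 in vitro; reads were PCR products and not independent molecules.

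The DMS treatment was read from the base at the stop. In cells, A made up 49.1% and 52.1% of stops 20 to 150 nt upstream of the 3′ end in the DMS libraries (replicates A and B) and 34.0% and 33.7% in the untreated ones. In refolded RNA, A made up 53.1% and 49.4% with DMS and 34.6% and 34.7% without, and in JYAC2 53.6% and 58.7% with DMS and 33.1% and 33.3% without. The other bases took smaller shares as that of A grew. In cells C made up 14.7% and 15.1% of stops with DMS and 17.3% and 17.5% without, G 13.1% and 12.5% with and 16.3% in both without, and T 23.1% and 20.3% with and 32.3% and 32.5% without, so that C was higher relative to G and T with DMS. NAI libraries had A at 34.3% and 34.2% of stops beside 32.9% and 33.3% in solvent. In JYAC7, replicate B had 54.5% with DMS and 34.6% without, while in replicate A the library labelled DMS had 34.1% and the library labelled untreated had 54.0%. These shares were not tested between groups, and their 95% Wilson intervals, which cover counting error only, spanned at most 0.065 percentage points.

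**Figure D1:**
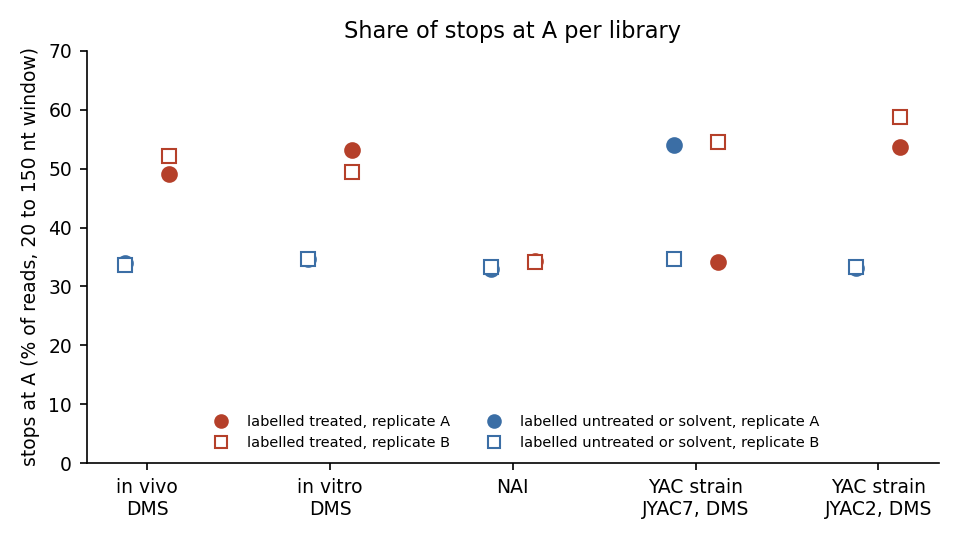
Share of reverse transcription stops at A (percent of reads 20 to 150 nt upstream of the 3′ end, vertical axis) in each of the 20 libraries mapped to S. cerevisiae, by experiment; red marks libraries labelled treated, blue those labelled untreated or solvent, filled circles replicate A and open squares replicate B. In JYAC7 the library labelled untreated A sits at 54.0% and the library labelled DMS A at 34.1%, the reverse of replicate B.

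How well a profile repeated set what the comparisons could show. A profile was the share of an isoform's reads that stopped at each position, treated minus its own control. The median Pearson r between replicates A and B was 0.207 over 16290 isoforms in vivo, 0.396 over 16878 isoforms in vitro and 0.426 over 20203 isoforms with NAI. It reached 0.738 in native D. hansenii (6135 isoforms) and 0.308 in native K. lactis (7002 isoforms). In JYAC2 it was 0.426 for host mRNAs and 0.379 for 54 insert isoforms. In JYAC7 it was -0.018 for host mRNAs and -0.023 for 102 insert isoforms with the libraries as labelled, against 0.636 and 0.562 with the libraries of replicate A exchanged. Within an experiment r rose with reads: in vivo the median was 0.106 for isoforms with 200 to 500 reads in their shallowest library and 0.758 for the 507 isoforms with at least 10000. Reads alone did not set the order of the experiments, since isoforms with 200 to 500 reads had 0.307 in vitro and 0.333 with NAI.

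Whether 3′ isoforms of the same gene differ in structure upstream of both ends is the question of the series' title. In vivo, the largest differences between the pair of most abundant isoforms lay in genes whose ends were far apart. At shared positions the longer isoform was read farther from its own end, by the distance between the ends. Effects of that distance on stops cannot be told apart here from differences in structure. TMA19, which encodes a ribosome-associated protein, had isoforms ending 102 and 209 nt after the stop codon (chromosome XI, minus strand, 334310 and 334203): each matched itself between replicates with r of 0.97 and 0.86, but r between the isoforms was 0.13. RPL6B, a ribosomal protein gene (chromosome XII, 1029925 and 1030015, 90 nt apart), had 0.71 and 0.80 within and 0.03 between its isoforms. XRN1, the cytoplasmic 5′ to 3′ exoribonuclease, had 0.62 and 0.92 within and 0.08 between isoforms 85 nt apart, and SAS10, PKR1, ARF2, PRE7 and LEU9 had differences of 0.44 to 0.65 with ends 22 to 100 nt apart. CRM1, the nuclear export receptor, and PAT1, a decapping activator, were the only of these 10 genes with closer ends, 9 and 2 nt apart, and had differences of 0.56 and 0.55.

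Over 2926 genes the in vivo r was 0.306 within and 0.277 between isoforms, a difference of 0.029 ± 0.003 (SE over genes; two-sided sign-flip permutation p = 1e-05, the smallest that 100000 permutations can give). In 15.3% of the genes (95% Wilson interval 14 to 16.6) both r between isoforms lay below both r within isoforms. If every order of these r were equally likely, the share would be higher than this. The same holds for the in vitro share over all genes (15.0%), but not for that with NAI (18.3%). Only against the simulated sets were the in vivo and in vitro shares over all genes high. Part of the mean difference in r arises from unequal depth alone. In 100 simulated sets both isoforms shared their profile. These sets gave a mean difference of 0.010 and at most 0.019, and 13.2% of genes apart and at most 15.0%. By distance, ends 1 nt apart gave 0.030 against a simulated 0.034, ends 2 to 3 nt apart 0.021 against 0.017, and ends 4 to 10 nt apart 0.014 against 0.016, none above the highest simulated set. By distance, 1 random pair was taken per gene. At 4 to 10 nt all 100 simulated sets had at least the observed 11.9% of genes apart (mean 14.8%). The sets thus ran high at near ends, and not exceeding them does not show that near isoforms were alike. Ends 11 to 30 nt apart gave 0.036 against 0.017 (highest simulated 0.026), although the share of genes apart, 15.1%, did not exceed the simulated sets there (mean 14.9%, highest 16.8%). Ends 31 to 100 nt apart gave 0.065 against 0.016 (highest 0.033), with 21.1% of genes apart (highest 19.0%). SOD1, the copper-zinc superoxide dismutase gene (chromosome X, minus strand), had its main ends at 65 and 71 nt after the stop codon (622485 and 622479), and r was 0.62 and 0.72 within and 0.67 between them.

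With NAI, the named genes again had well separated ends. TAF14, a subunit of several transcription complexes, had r of 0.82 and 0.84 within and 0.14 between isoforms 36 nt apart. RPS29B (51 nt apart, difference 0.59) and RPL16A (36 nt apart, 0.54) encode ribosomal proteins, SEC14 (148 nt, 0.53) a phospholipid transfer protein, URA5 (90 nt, 0.48) an orotate phosphoribosyltransferase and IDH1 (96 nt, 0.47) a subunit of isocitrate dehydrogenase. PIN3, YBL036C, CWH43 and AIM7 had differences of 0.48 to 0.50 with ends 17 to 161 nt apart. Over 2976 genes r was 0.481 within and 0.428 between isoforms, a difference of 0.053 ± 0.002 (SE; permutation p = 1e-05, the smallest possible) against a simulated 0.009 and at most 0.014. In 18.3% of genes the isoforms were apart, against at most 12.2% in the simulated sets. Differences did not exceed the highest simulated set for ends 1 nt (0.028 against 0.034) and 2 to 3 nt apart (0.025, highest simulated 0.026), and above it for ends 4 to 10 nt (0.034, highest 0.024), 11 to 30 nt (0.059, highest 0.024) and 31 to 100 nt apart (0.107, highest 0.028). SOD1 had 0.67 and 0.67 within and 0.62 between its isoforms.

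In RNA refolded in vitro, RPL6B, XRN1 and LEU9 were again among the 10 genes with the largest differences, at 0.81, 0.69 and 0.65, and TAF14, named also with NAI, had 0.41. PDR5, which encodes a multidrug transporter, had r of 0.99 and 0.83 within and 0.26 between isoforms only 3 nt apart. YCP4, the ribosomal protein genes RPL32 and RPS18A, ATP18 and TSC13 had differences of 0.40 to 0.65 with ends 16 to 79 nt apart. Over 2888 genes the difference was 0.030 ± 0.003 (SE; permutation p = 1e-05, the smallest possible) against a simulated 0.009 and at most 0.014, and 15.0% of genes were apart against at most 12.2%. Ends up to 10 nt apart gave 0.016 to 0.019, not above the simulated sets, and for ends 1 nt apart all 100 sets lay higher than the observed 0.019. Sets that all lie above the data ran too high, so they cannot tell whether isoforms with such near ends differed. The share of genes apart at 4 to 10 nt, 12.9%, lay just above the highest simulated 12.8%. Ends 11 to 30 nt apart gave 0.036 (highest simulated 0.026) and ends 31 to 100 nt apart 0.072 (highest 0.027). SOD1 had 0.93 and 0.95 within and 0.89 between its isoforms.

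**Figure D2:**
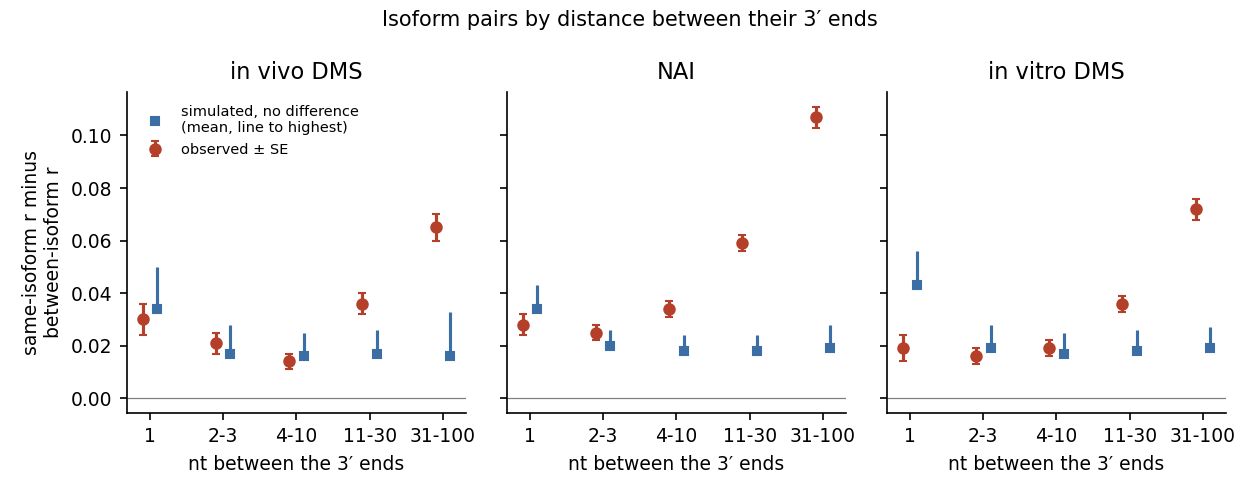
Mean r within isoforms minus mean r between isoforms of the same gene (vertical axis, no unit) by the number of nt between their 3′ ends (horizontal axis), for in vivo DMS, NAI and in vitro DMS; red circles are observed means ± SE over genes, blue squares the mean of 100 simulated sets with no difference and the line reaches the highest set. Observed mean differences lie above the simulated range at 11 nt and more with DMS and at 4 nt and more with NAI. At 1 nt in vitro all 100 sets lie above the observed mean, so the simulated range does not show that isoforms with near ends were alike.

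The genes apart were shared only in part between experiments. Across 2077 genes measured in both, 60 were apart in vivo and in vitro where independent calls would give 44.1, and the differences correlated with Spearman rho 0.069 across genes (permutation p = 0.00183). In vivo and NAI shared 58 where 48.2 would be independent (rho 0.104, p = 1e-05, the smallest possible), and in vitro and NAI 64 where 49.3 would be (rho 0.050, p = 0.0314). Unequal depth of the isoforms recurs between experiments, and 100 simulated sets in which they shared their profile gave a mean rho of 0.009 in vivo and in vitro (1 set reached the observed value), 0.005 in vivo and with NAI (0 sets) and 0.012 in vitro and with NAI (10 sets), and at most 39, 36 and 34 shared genes. Over all genes the simulated sets called fewer genes apart, on average 13.2% in vivo, 10.8% with NAI and 10.6% in vitro. The observed shares were 15.3%, 18.3% and 15.0%. Shared counts of the simulated sets are thus lower even where calls are independent. Genes are not independent replicates, and these 3 p-values were not adjusted for one another. The highest ratios of r between over r within isoforms belonged to AHC2, YPT7, PHB2, LDB7 and RNR2 in vivo, FOL2, IRC22, CFF1, IOC4 and BCH1 with NAI, and PRE3, SML1, RAD27, APL2 and PRE7 in vitro. In each of them at least 1 isoform had r of at most 0.04 between replicates.

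Both probes were compared at A and C positions of the most abundant isoform of 3530 genes. In vivo DMS profiles matched themselves with r of 0.359 and NAI profiles with 0.529, and r between the probes was 0.221. Corrected for these replicate values the correlation was 0.508. The mean difference of within-probe over between-probe r was 0.223 ± 0.004 (SE; permutation p = 1e-05, the smallest possible). Among the 391 genes with at least 5000 reads the corrected value was 0.447, so depth did not bring the probes together. It was 0.741 for treated libraries without subtraction of their controls, and the cause of this rise was not tested.

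Refolded RNA was compared with RNA in cells to ask how far the profile depends on the cell. Genes whose in vivo and in vitro profiles had least in common included ADF1 (chromosome III, end 23990, 65 nt after the stop codon; r of 0.32 in vivo, 0.40 in vitro and -0.08 between), NCE102 (0.43, 0.83 and -0.01), which encodes an eisosome protein, APS2 (0.37, 0.92 and 0.02), a clathrin adaptor subunit gene, and YCF1 (0.93, 0.60 and 0.02), a vacuolar glutathione conjugate transporter gene. PBP4, ASI1, SRP21, GCS1, CAP1 and PRY3 completed the 10 lowest, with r between settings of -0.03 to 0.01, although in vivo replicates of PBP4 had r of only 0.06. The highest ratios belonged to RDI1, ADE17, MIC12, CEX1 and SEC4, whose in vivo r between replicates was at most 0.02. SOD1 (end 622479) had 0.84, 0.97 and 0.78.

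Over 3675 genes r was 0.325 in vivo, 0.476 in vitro and 0.332 between settings. The difference of 0.068 ± 0.003 (SE; permutation p = 1e-05, the smallest possible) exceeded the 0.013 of simulated sets with shared profiles (highest 0.018), and the corrected correlation was 0.844, against a simulated 0.985. It was 0.096 for the 1501 genes with at least 1000 reads and 0.144 for the 348 with at least 5000. Among those with at least 1000 reads, chaperone and heat shock genes stood apart: 18 of them had a difference of 0.228, against 0.096 for all such genes (permutation of list membership, two-sided, adjusted p = 0.0109 over 13 lists). The 135 cytosolic ribosomal protein genes had 0.130 (adjusted p = 0.0767), glycolysis and fermentation genes 0.171 and cell wall and secreted protein genes 0.157 (both 0.195). Ribosome biogenesis genes had 0.058 (0.338), proteasome genes 0.059 (0.479) and genes of poly(A) tail binding, deadenylation and decapping 0.052 (0.516). Translation factors (0.126), respiratory chain and ATP synthase genes (0.120), histones (0.072), amino acid biosynthesis (0.097), ergosterol biosynthesis (0.1) and mitochondrial ribosomal protein genes (0.088) had adjusted p of 0.538 to 0.957. The random lists were not matched on reads, and the difference grew with reads.

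The place of the difference was sought in the ratio of stops 20 to 60 nt to stops 61 to 150 nt upstream of the end. DMS raised this ratio in cells, by a median log2 of 1.11 and 0.56 in replicates A and B, and lowered it in refolded RNA, by -0.55 and -0.72. This holds within 150 nt only. Over all stops the median distance from the end was shorter with DMS in refolded RNA too, at 154 and 155 nt against 163 and 167 nt untreated. In cells it was 119 and 126 nt with DMS and 138 and 134 nt untreated. Untreated libraries thus already differed between settings, and whether this shaped the interaction was not tested. The interaction had a median of 1.51 over 13209 isoforms of 3676 genes, with quartiles of 0.61 and 2.37. Its median lay between 1.27 (amino acid biosynthesis, 296 isoforms) and 1.71 (poly(A) tail binding, deadenylation and decapping, 106 isoforms) in all 13 lists: 1.54 in cytosolic ribosomal protein genes and in histones, 1.65 in mitochondrial ribosomal protein genes, 1.70 in glycolysis and in proteasome genes, 1.56 in translation factors, 1.62 in chaperones, 1.61 in ribosome biogenesis, 1.48 in the respiratory chain, 1.34 in cell wall genes and 1.36 in ergosterol genes. RPL24A (end 437333 on chromosome VII) had an interaction of 7.12 ± 0.63 (SE) and SRP54, the GTPase subunit of the signal recognition particle, 6.22 ± 0.68, while the ATP synthase gene ATP5 had -5.91 ± 1.2 and TRP1, of tryptophan synthesis, -6.50 ± 1.3. These 4 genes were chosen after their values were seen, and none passed the test. The SOD1 isoform ending at +71 had 1.45 ± 0.75 (adjusted p = 0.291).

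No isoform passed the limma test on these 8 libraries (lowest adjusted p 0.221), whereas 2849 isoforms had an unadjusted p under 0.05. With 2 residual degrees of freedom the test recovered 0 of 100 isoforms changed by log2 8 in simulated data and 5157 of 6604 when that many changed by log2 4 (145 false calls), but 0 of 6604 changed by log2 2 or 1.5, so a change of the size of the observed median would not have been called. The count was 0 with and without the replicate block.

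Pab1 was immunoprecipitated to ask which mRNAs it carries more or less than the average mRNA. Among the 20 named genes, MEF2 (log2 of 1.24 ± 0.24, SE), which encodes a mitochondrial translation factor, RPL34B (1.3 ± 0.26), a ribosomal protein gene, RTT101 (1.23 ± 0.25), a cullin gene, and SRP21 (1.3 ± 0.27), of the signal recognition particle, were higher in the immunoprecipitate by 0.53 to 1.73 in every culture. NMA1 (1.63 ± 0.33), SPR2 (1.43 ± 0.34), NAT5 (1.38 ± 0.28), AIM24, GAL2 (1.3 ± 0.27) and CYT1 (1.3 ± 0.32), the cytochrome c1 gene, owed most of their rise to 1 culture: they lay at 3.25 to 5.00 in myc culture B but at 0.05 to 0.48 in the V5 culture. Except in NMA1, a low myc B input gave this ratio. In reads per M, NAT5 inputs were 898.8 in myc A, 80.6 in myc B and 872.7 in V5. Its immunoprecipitates were 1543.8, 1020 and 903.9. Inputs of SPR2, AIM24, GAL2 and CYT1 were 1 to 24.1 in myc B and 34.3 to 226 in the others. Myc B immunoprecipitates of these genes lay below those of myc A. NMA1 had 132.9 in the myc B immunoprecipitate against 58.4 (myc A) and 24.4 (V5), with inputs of 11.8, 22.7 and 19.8. Some falls were more even than these rises. TAO3 (-1.65 ± 0.30), a scaffold gene of a morphogenesis kinase network, TUL1 (-1.59 ± 0.32), a ubiquitin ligase gene, and SEC16 (-1.46 ± 0.27), needed for COPII vesicle formation, had log2 ratios of -0.94 to -2.13 in every culture. URA2, of pyrimidine synthesis, had -1.34, PDR5 -1.3, ESL2 -1.29, MOT1 -1.32, the ferroxidase gene FET3 -1.34, NST1 -1.3 and DCK1 -1.51. In myc A, myc B and V5, DCK1 had -0.58, -2.18 and -1.73, NST1 -0.38, -1.95 and -1.6, and FET3 -1.43, -2.04 and -0.55. Here too the myc B input stood out in FET3 (12113.3 reads per M against 3521.7 in myc A and 2831.5 in V5). In DCK1 it was 985.8 against 316.2 and 366.7. SOD1 had 0.15 ± 0.26 (adjusted p = 0.78). PAB1 itself lies on chromosome V, which was listed throughout only without myc culture A, and had 0.07 ± 0.33 there (adjusted p = 0.958).

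Of 3012 genes tested on the 8 chromosomes that all 6 libraries listed throughout, a restriction set after a fit on 10 chromosomes had called 0 genes by edgeR (394 at an unadjusted p under 0.05), 104 were higher and 139 lower in the immunoprecipitate (edgeR quasi-likelihood test with the culture as a block, Benjamini-Hochberg adjusted p under 0.05; 664 genes at an unadjusted p under 0.05). Without the block, which pairs each immunoprecipitate with its own input, 0 genes passed and 292 had an unadjusted p under 0.05, and DESeq2 with the block called 171. The count was 57 without myc culture A, 380 without myc culture B and 26 without the V5 culture, so every culture moved it by more than 1.5 times. The log2 ratio fell with coding length (Spearman rho -0.597 across genes, permutation p = 1e-05, the smallest possible; genes are not independent replicates): the median coding length was 514 nt among the higher genes, 2841 nt among the lower ones and 1239 nt among all.

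**Figure D3:**
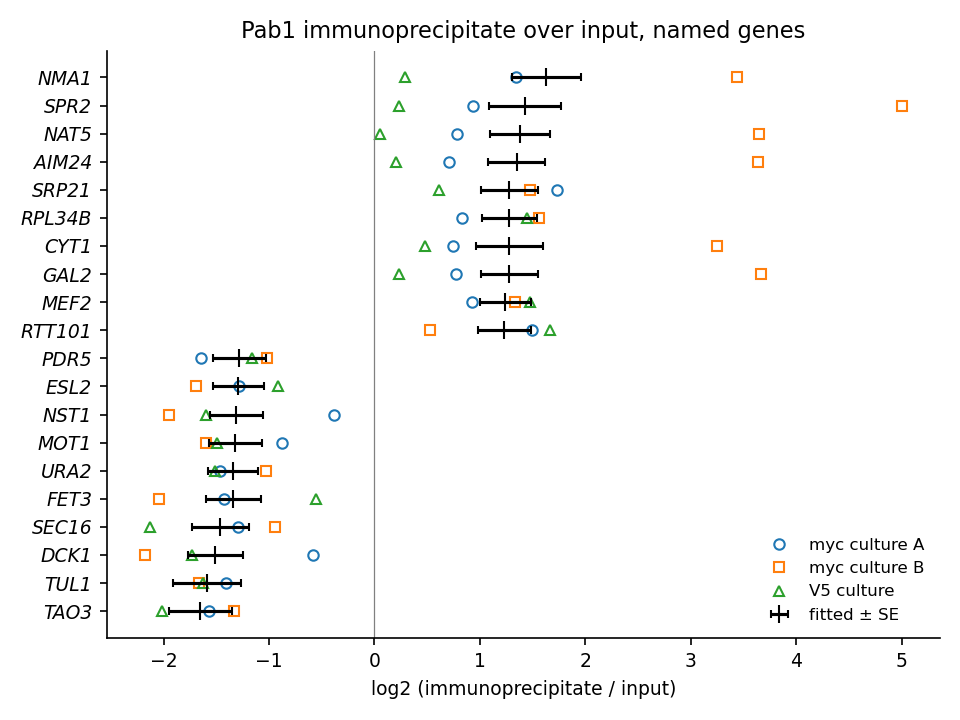
Log2 ratio of Pab1 immunoprecipitate over input (horizontal axis) for the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold and moving the same way in all 3 cultures; open symbols are the cultures and black bars the fitted value ± SE. NAT5, at 3.65 in myc culture B, 0.78 in myc culture A and 0.05 in the V5 culture, shows how single cultures set several of the rises. Its myc B value came from a low input, at 80.6 reads per M against 898.8 in myc A and 872.7 in V5.

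By gene list, 6 of 77 cytosolic ribosomal protein genes were higher and 0 lower (6 higher and 0 lower adjusted over the list alone), with a list median of 0.39. They included RPL34B and RPS12 (1.1 ± 0.26). Of 39 mitochondrial ribosomal protein genes 3 were higher and 0 lower (8 and 0 over the list alone), among them MRPL39 (0.92) and MRPL19 (0.82), with a median of 0.31, although both lay near 0 in myc culture B (-0.04 and 0.06). Of 22 respiratory chain and ATP synthase genes 5 were higher and 0 lower (5 and 0 over the list alone), among them CYT1 and COX12 (1.21 ± 0.25), with a median of 0.30. Tested against all other genes with camera at a preset correlation, these 3 lists were higher, with adjusted p of 2.92e-08, 0.000245 and 0.0101. With an estimated correlation the adjusted p was 0.684 for each. Their median coding lengths were 435, 654 and 459 nt, so these lists held short genes, and genes of like coding length had medians of 0.39, 0.26 and 0.34.

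The other lists passed camera in neither form. Chaperone and heat shock genes had 1 higher (HSP10, 0.99) and 0 lower of 14 (1 and 1 over the list alone), ribosome biogenesis genes 2 higher (IMP4, NOP53) and 3 lower of 38 (2 and 3), among the latter UTP10 (-0.89) and RRP5 (-0.82). Cell wall and secreted protein genes had 0 higher and 3 lower of 27 (1 and 5), among them PLB2 (-1.07) and SIM1 (-0.83). Glycolysis and fermentation had 1 lower of 9, PDC1 (-0.79), which lay at 0.50 in myc culture B against -1.34 and -1.46 in the others. Translation factors had 1 lower of 19, PRT1 (-0.74), amino acid biosynthesis 1 lower of 26, SER1 (-0.78), and ergosterol biosynthesis 1 lower of 16, HMG1 (-0.82). In the proteasome list RPN13 (0.71) was higher among 14. Histones (0 of 5) and genes of poly(A) tail binding, deadenylation and decapping (0 of 16; median -0.01) had no call by edgeR. Adjusted over the list alone, the calls of these lists from glycolysis on were the same in number. Median and mean differed in sign in glycolysis (0.14 and -0.03), the proteasome (-0.08 and 0.03) and the poly(A) list (-0.01 and 0.05). By fry, which asks whether a list moves on balance, ergosterol biosynthesis moved down (adjusted p = 0.0494, list median -0.16) and the other lists had adjusted p of 0.102 or more.

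Within genes, isoforms rarely differed in Pab1 association. GSP1, the yeast Ran GTPase gene, had an isoform ending 205 nt after the stop codon (chromosome XII, minus strand, 720566) at log2 1.40 relative to the gene, with ratios of 1.46, 2.90 and 1.29 in the 3 cultures, while its lowest isoform, ending 142 nt after the stop codon, had -1.07, -0.16 and -0.61. CCW12, a cell wall mannoprotein gene with 56 isoforms, ranged from 1.73 to -0.79, but both isoforms had few reads (29.7 and 22 on average) and values that differed widely between cultures: the highest isoform had 2.04, 6.66 and 0.94 in myc A, myc B and V5 (isoform adjusted p = 0.68), and the lowest -0.53, 0.59 and -5.17 (adjusted p = 1). These were the 2 genes of 2133 that passed edgeR's test of isoform differences (adjusted p = 0.016 for both), and 70 genes had an unadjusted p under 0.05. APT1 and GID8 (both 0.0894), YOL036W (0.102), SUI1 and TRP3 (both 0.113), RPS3 (0.383), MCH4 (0.545) and CEX1 (1) did not pass, nor did SOD1 with 29 isoforms (adjusted p = 1). Without the culture block 0 genes passed, without myc culture A 0, without the V5 culture 1, without myc culture B 3 that included neither gene, with no read filter 2 that included neither, and with ends within 5 nt merged 5. The test recovered 9 of 195 genes with a simulated 2-fold isoform difference (3 false calls, more than the 2 genes called here) and 178 of 191 with an 8-fold one (11 false calls), so small differences were not detectable at this depth.

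The series' title ties structure to Pab1 binding, so the ratio of immunoprecipitate to input was set against net DMS reactivity near the end. Across 6503 isoforms of 1405 genes the within-gene Pearson r was 0.014 (permutation p = 0.315) and Spearman rho 0.011 (p = 0.412), and across all isoforms pooled r was 0.005 and rho -0.008. For the 10 SOD1 isoforms r was 0.071. Neither isoforms nor genes are independent replicates. Noise limited this comparison: within genes the ratio correlated by 0.090, 0.119 and 0.041 between pairs of cultures, and reactivity by 0.457 between replicates. With windows of 20 to 50 and 51 to 150 nt r was 0.029 (permutation p = 0.0446), and stops of untreated libraries alone gave 0.030 (p = 0.0372).

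In the SOD1 library, 5 nt at positions +66 to +70 after the stop codon were randomized, just upstream of the main 3′ end at +71. The base next to that end went with how often it was used. Pentamers with T at +70 had 48.4% and 49.8% of their reads ending at +71 (replicates A and B; share of reads ending at +71 or later), and those with A had 21.2% and 21.8%. C and G lay between, at 38.2% and 37.0% and at 35.2% and 35.7%. The base at +70 accounted for 35.7% of the variance of this share over 579 pentamers, the base at +69 for 12.5%, and the bases at +66 and +67 for 3.1% and 3.8% (adjusted permutation p = 1.43e-05, 1.43e-05, 0.000478 and 7.5e-05 over 10 tests), while +68 with 1.2% did not pass (0.0761). G at any of the 5 positions went with farther ends, with means of 76.3 to 76.7 against 74.4 to 76.1 for the other bases. An end at +70 next to A cannot be placed exactly, because the poly(A) tail also starts with A; the base at +71 is C, so that the base at +70 does not blur the share ending at +71.

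Single pentamers repeated between replicates. AAAAA ended on average at +73.1 and +73.3, CAAAA at +73.3 and +73.0 and TTGTT at +73.5 and +73.0, whereas GAGGG ended at +87.6 and +86.3, GGGGG at +85.9 in both and AGATG at +85.0 and +86.1. The mean end correlated between replicates over 579 pentamers with Pearson r of 0.774 and Spearman rho of 0.597 (permutation p = 1e-05, the smallest possible). Its mean was +75.6 with an SD of 2.6 nt between pentamers, against 1.3 nt between replicates. The libraries held 1013 and 1001 of 1024 possible pentamers, of which TTTTT was the most read (68016 and 70513 reads). The genomic pentamer, ATTTT, had 0 listed reads in both replicates.

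**Figure D4:**
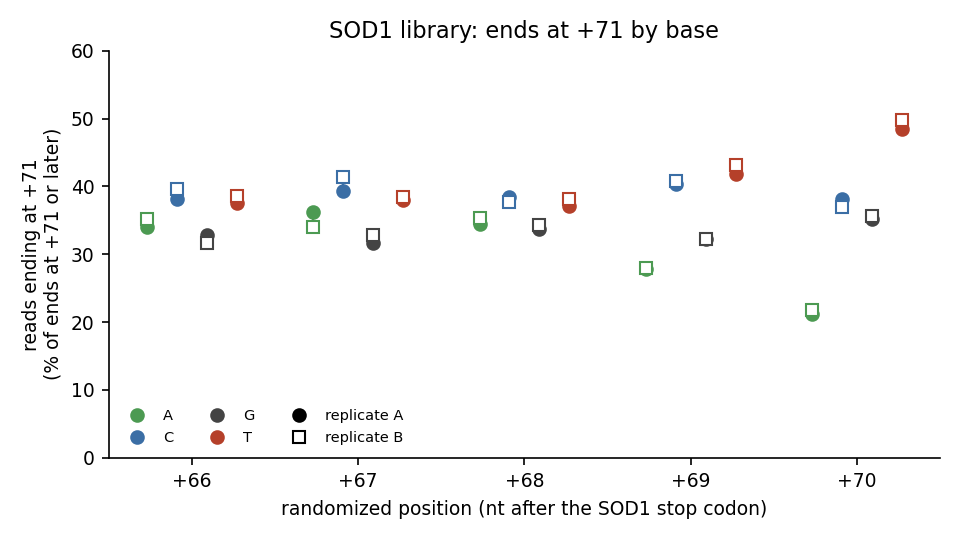
Percent of SOD1 library reads ending at +71, among reads ending at +71 or later (vertical axis), by the base at each randomized position (horizontal axis, nt after the SOD1 stop codon); points are means over pentamers, filled circles replicate A and open squares replicate B, with colours for bases. At +70 pentamers with T have 48.4% and 49.8% and those with A 21.2% and 21.8%.

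Reactivity upstream of the randomized stretch did not follow the pentamer detectably. Over 496 pentamers and the 66 A and C positions in the window, r was 0.205 between replicates of the same pentamer and 0.201 between different pentamers of like depth, a difference of 0.003 ± 0.009 (SE; one-sided permutation p = 0.36). No randomized position had a base effect on the profile that repeated between replicates (adjusted permutation p of 0.347 to 0.515 for the 5 positions). For the 48 pentamers with at least 2000 reads the difference was 0.051 ± 0.029 (permutation p = 0.0126), a subset taken after the result was seen.

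Transcripts of D. hansenii were compared between their own cells and JYAC7 to ask whether a profile is kept in another species' cell. Of the 26 clusters of 3′ ends compared, the 1 with the most reads at its compared end lay at 1195639 on contig Deha2D (minus strand). It had r of 0.99 between native replicates and 0.44 between hosts with the JYAC7 libraries as labelled, against 0.98 with the library labelled untreated A and the library labelled DMS A exchanged. A cluster with more untreated reads, from 1282604 to 1282904, was not among the 26. The clusters at 1300044 and 1191740 had 0.48 and 0.46 as labelled and 0.99 and 0.95 exchanged. The cluster at 1195820 had 0.65 between hosts after the exchange, below its 0.88 between native and 0.96 between YAC replicates. The cluster at 1253440 had 0.93 between native replicates and 0.20 both between YAC replicates and between hosts, so poor repeatability in the YAC strain leaves open whether it differed. Over 26 clusters as labelled, r was 0.808 between native replicates, -0.029 between YAC replicates and 0.311 between hosts (difference 0.078 ± 0.022, SE; permutation p = 0.00098), and no direction can be drawn from it, because the A share goes against the labels of JYAC7 replicate A. Exchanged, the values were 0.808, 0.670 and 0.689, with a difference of 0.050 ± 0.019 (p = 0.00561), which 2 of 100 simulated sets with shared profiles reached.

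K. lactis transcripts were compared between native cells and JYAC2. The most read cluster, at 438107 on contig Klla0C (minus strand), had r of 0.90 between native replicates, 0.88 between YAC replicates and 0.86 between hosts. The cluster at 471202 had 0.73, 0.74 and 0.52, and that at 399455 had 0.25, 0.15 and 0.08. Over 20 clusters r was 0.332 between native replicates, 0.417 between YAC replicates and 0.340 between hosts. The difference of 0.035 ± 0.026 (SE over clusters, p = 0.194 by sign-flip permutation over clusters) did not pass, and 15 of 100 simulated sets with shared profiles reached it. It was -0.005 with positions 20 to 100 nt.

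The choice of 3′ ends differed between hosts. In D. hansenii clusters the distance between the end shares of both hosts (total variation, 0 for the same shares and 1 for none in common) averaged 0.561, against 0.061 between native replicates and 0.147 between YAC replicates, an excess of 0.457 ± 0.024 (SE, 79 clusters; permutation p = 1e-05, the smallest possible) that was above 0 in 78 clusters. Ends lay downstream in the YAC host in 59 of 79 clusters, on average by 7.2 nt (permutation p = 0.00021). In K. lactis clusters the distance was 0.353 between hosts, 0.148 between native and 0.264 between YAC replicates, an excess of 0.147 ± 0.014 (62 clusters; permutation p = 1e-05, the smallest possible), with ends downstream in the YAC host in 39 clusters, on average by 3.2 nt (p = 0.00456). The excess was larger in D. hansenii by 0.310 (permutation of species labels, p = 1e-05, the smallest possible), while the difference of the shifts, 3.9 nt, did not pass (p = 0.0948). Clusters of an insert share the same libraries, so here and in the profile comparisons above they are not independent replicates of a host or species. With the JYAC7 libraries of replicate A exchanged the D. hansenii excess was 0.471. Gene annotation of these species was not used here, so clusters are named by position.

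**Figure D5:**
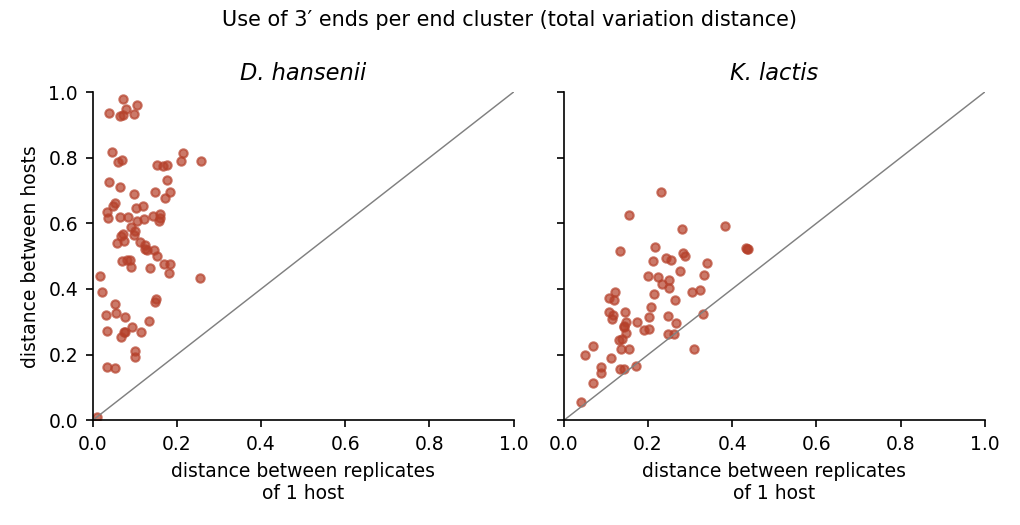
Total variation distance of 3′ end use between native and YAC host (vertical axis) against the mean distance between replicates of the same host (horizontal axis), 1 point per cluster of 3′ ends, for 79 D. hansenii and 62 K. lactis clusters; the line marks equal distances. In D. hansenii 78 clusters lie above the level of their replicates.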

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

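The tests of other splits of the Pab1 libraries, of JYAC7 replicate A, and of exchanged labels and carried-over reads for D. hansenii ends were chosen after the result was seen.

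Transcripts of long genes were low in the Pab1 immunoprecipitate, and the tables argue against several technical causes of the whole trend. Among genes with at least 500 mean reads rho between coding length and the ratio was -0.711, given input abundance it was -0.626 and given GC content -0.601, and the culture nearest 0 had -0.261. The enrichment of cytosolic ribosomal protein genes may be part of it, since the list minus genes of like coding length was 0 (medians of 0.39 each). RNA fragmentation and loss of long mRNAs during precipitation stay open. No biological explanation was tested.

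In JYAC7 replicate A, the library labelled untreated had 54.0% of its stops at A and the library labelled DMS had 34.1%. Failed DMS treatment alone would leave the library labelled untreated low, which its 54.0% argues against. An exchange of both libraries is consistent with these values, and with replicate r of 0.636 after it. The file names read as exchanged relative to the titles. Median stop distances were 96 nt in the library labelled untreated A and 132 nt in that labelled DMS A. Replicate B had 95 nt with DMS and 137 nt without. These values, the A shares and the replicate r go with the file names and argue against the titles, although no record of the samples settled it.

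D. hansenii transcripts ended elsewhere in the YAC host than in native cells, with an excess distance larger than that of K. lactis transcripts by 0.31 (permutation p = 1e-05, the smallest possible), the difference between the groups that drew attention. The permuted clusters are not independent replicates. Native libraries thinned to the YAC depth had a distance of 0.066, which argues against depth. With the JYAC7 libraries of replicate A exchanged the excess was 0.471, which argues against exchanged labels. The distance between hosts exceeded that between YAC replicates in 98.7% of clusters, which restates the excess. Native reads carried over into the YAC libraries would make the hosts more alike. The mean distance of 0.561 between hosts, against 0.147 between YAC replicates, therefore argues against them as its cause. A hypothesis is that the host's cleavage machinery sets the ends, which may also reflect strain or growth differences between the libraries; neither was tested.

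The median DMS effect on stops near the 3′ end was above 0 in both replicates in vivo and below 0 in both in vitro, a difference of 1.51 on the log2 scale that was not tested as a median. Reads of S. cerevisiae made up 1.104% (95% Wilson interval 1.098 to 1.109) of the D. hansenii DMS A library and 0.037% of the lowest native D. hansenii library. They made up 0.727% (0.723 to 0.731) of the K. lactis DMS A library and 0.103% of the lowest. The S. pombe spike-in reached 1.284% (1.281 to 1.287) and was lowest at 0.298%.

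Of the 10 splits of the 6 Pab1 libraries into 3 and 3, 1 gave as many genes as the real 243, namely the real split itself, and the highest other gave 5. For isoforms 3 of 10 splits gave at least the real 2 genes and the highest other gave 60. The splits with 60, like those with 5 above, part the immunoprecipitate and input of only 1 culture. With the culture as a block they compare those libraries alone, so their counts do not measure chance. The other 3 splits that part all pairs gave 0 in both cases by edgeR. With 10 splits a share under 0.05 cannot be reached.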

How the results depend on the processing

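The exchange of JYAC7 libraries for replicate agreement, A and C positions only, isoforms within 1.5-fold in reads, both other choices of chromosomes and the unmatched SOD1 permutation were chosen after the data were seen. Of the alternative values of results that answer a comparison, 142 kept direction and side of the threshold, 37 moved, 3 became significant and 8 reversed. Of those of single named genes and lists, 595 stayed, 184 lost significance, 132 moved and 5 became significant. For the changes below, the cause was not tested unless fewer samples or genes explain it.

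With treated libraries alone, median replicate r was 0.418 in vivo, 0.732 in vitro, 0.865 with NAI, 0.899 in D. hansenii, 0.669 for JYAC2 host, 0.638 for JYAC7 host and 0.597 for JYAC7 insert mRNAs. With Spearman rho it was 0.414 in D. hansenii, 0.039 for JYAC7 host and 0.072 for JYAC7 insert mRNAs, and with 100 reads 0.004 for JYAC7 host mRNAs. With the libraries exchanged it was 0.636 (host) and 0.562 (insert). Genes apart were 21% in vivo with Spearman rho, 17.6% with treated libraries alone and 16.8% at like depth, 40.7% with NAI treated alone, and 20.1% (Spearman) and 19.2% (treated alone) in vitro. Within replicates, r between isoforms was 0.449 and 0.478 with NAI and 0.462 in vitro A, and r between in vivo and in vitro was 0.329 in A.

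The corrected r of in vivo and in vitro profiles was 0.885 with 20 to 100 nt, 0.726 with Spearman rho, 0.909 treated alone and 0.859 at A and C. That of DMS and NAI was 0.485 with 500 reads, 0.550 with 20 to 100 nt, 0.565 with Spearman rho and 0.741 treated alone. The K. lactis difference was -0.005 with 20 to 100 nt.

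Pab1 genes numbered 0 without the replicate block (292 at an unadjusted p under 0.05, edgeR), 26 to 380 with 1 culture left out (57 without myc A, 380 without myc B, 26 without V5), 36 with the most abundant isoform, 119 without myc A on all chromosomes, and 0 on 10 chromosomes (394 unadjusted). DESeq2 called 171. Genes with isoform differences numbered 0 without the replicate block (34 unadjusted), 0 to 3 with 1 culture left out (0 without myc A, 1 without V5), 5 with ends merged, 0 without myc A on all chromosomes (51 unadjusted) and 0 on 10 chromosomes (81 unadjusted). List tests were not run without the block. For stops near the 3′ end the block changed no call, the replicate numbers did not pair (r of 0.003 and -0.009), and limma called 0 in every setting (2849 unadjusted in the main one).

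Pab1 against reactivity was 0.029 with windows of 20 to 50 nt and 0.030 with untreated libraries, and the SOD1 difference was 0.019 with the unmatched permutation. Leaving out a replicate could not be run for r between replicates or for end use. The run without the genomic SOD1 pentamer was not made, because that pentamer had 0 listed reads. Depth limits single isoforms: in vivo median r was 0.106 at 200 to 500 reads.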

Other observations

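The tests of deep pairs with far ends, of JYAC2 pairs at least 11 nt apart, of JYAC2 pairs against simulated sets and of base content other than A were chosen after the result was seen.

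Genes whose isoforms differed in vivo tended to differ also in JYAC2, another strain. Across 1378 genes the within minus between r correlated with Spearman rho 0.157 (permutation p = 1e-05, the smallest possible), and with ends at least 11 nt apart, 519 genes, with 0.280. Unequal depth of the 2 isoforms recurs in both, but 100 simulated sets in which the isoforms shared their profile gave a rho of at most 0.101, and with ends at least 11 nt apart of at most 0.129. Both experiments called 60 genes apart, where independent calls would give 33.3 and the simulated sets gave 18.0 on average and at most 33. Simulated in vivo sets called fewer genes apart, 13.2% on average against 15.3% over all genes. Their shared counts are thus lower even where calls are independent. Genes are not independent replicates. For 84 genes with at least 1000 reads and ends 31 to 100 nt apart the in vivo difference was 0.073 ± 0.018 (SE), no lower than the 0.065 without this read minimum. The simulation put in vivo reads at this distance at 115.3 per independent molecule, so 1000 reads were few molecules. No simulated sets were made for these 84 genes, so the read minimum cannot exclude noise. Without it, the 0.065 lay above the highest simulated 0.033.

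A hypothesis was that isoforms with more A in their last 60 nt are higher in the Pab1 immunoprecipitate. The within-gene r was 0.007 (permutation p = 0.479, 14751 isoforms of 2133 genes), which argues against it. C had -0.111 and U 0.091 (both permutation p = 1e-04, the smallest that 10000 permutations can give, adjusted 0.0002), and G -0.028 (p = 0.0038, adjusted 0.00507). Of 1735 genes with at least 3 isoforms, longer isoforms had the higher ratio in 801 and the lower in 934.

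None of the 13 lists lay outside 2000 random lists of like coding length in its median Pab1 ratio. The lowest percentiles were 6.8 for 14 proteasome genes (-0.08 against 0.09), 10.8 for 5 histone genes (0.06 against 0.29) and 11.2 for 16 ergosterol genes (-0.16 against -0.01). Without myc culture A, on all chromosomes, edgeR called 3 of 137 cytosolic ribosomal protein genes and 4 of 41 respiratory chain genes higher, but 0 of 72 mitochondrial ribosomal protein genes. The median of the mitochondrial list was 0.38 there, against 0.31 for its 39 genes in the main fit. Of cell wall genes 1 of 40 and of histones 1 of 11 were higher, and of ribosome biogenesis genes 1 of 68 was lower.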
